A study of Mus musculus with 2 samples.

How the data were processed

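Single-cell RNA-seq libraries (10x Genomics) of sorted LSK CD150+ mouse bone marrow cells were used, 1 labelled RUNX1 WT and 1 labelled RUNX1 KO. The deposited values are UMI counts per gene and barcode, made by the authors with Cell Ranger 2.1.1 against mm10, per the submitters' processing notes, while the file headers name software version 3.1.0. Per the labels' protocols the libraries followed the 3′ v2 kit. Counts were used as deposited. Groups were taken from the genotype labels. How many animals gave each library is not stated in the sources used here.

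Cells with at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes were kept, which left out 497 of 9969 WT barcodes and 629 of 11398 KO-labelled barcodes. Doublets were not removed. Scrublet (in scanpy 1.11.5) called 610 WT cells (6.44%) and 0 KO-labelled cells, so it did not work in the latter. UMIs were summed over cells per library and scaled to the library total (CPM), and CPM ratios were computed from the deposited counts. Where a library had 0 counts it was set to 3 counts. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. No test, p-value or standard error was made, because there was 1 library per genotype. Genes at 20 CPM or more in either library were counted when the ratio was at least 2 either way.

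Gene lists were fixed before the data were examined. For each, the median log2 ratio over members at 5 CPM or more in either library was placed among 10000 random lists of the same size matched on expression in 20 bins. The named genes were the 12 highest and 12 lowest ratios among genes at 20 CPM or more with a UMI in at least 10% of cells of the library where they were higher, leaving out ribosomal protein, mitochondrially encoded, sex-linked, haemoglobin and unnamed genes. Also named were the RUNX list, a set of marker genes and up to 4 members of each other list. Those were the members with the largest ratios either way among members at 20 CPM or more, or at 5 CPM where too few passed. Some genes that the rule names are counted but not reported here. Mmrn1, Gp5, Cdkn1c and other list members outside that rule are given as examples chosen after their values were seen. Gene positions are from GENCODE M21 on GRCm38, the mm10 build, matched by gene ID.

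For shares of cells each cell was thinned without replacement to 3000 UMIs. For clustering, counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were used without ribosomal, mitochondrial and sex-linked genes and without genes that differed 1.5-fold or more between libraries, with 30 principal components, 20 neighbours and Leiden resolution 0.8 (leidenalg 0.10.2). Clusters were named from marker lists fixed beforehand, with genes that differed between libraries included. Male cells were those with a UMI of Ddx3y, Eif2s3y, Kdm5d or Uty and no Xist UMI, and female cells those with at least 2 Xist UMIs and none of these. That split was chosen after the data were seen.

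The ratio, count and list steps were tested on simulated sums with 200 genes changed. Of these, 199 were at 20 CPM or more in the simulated sums, beside 5506 unchanged genes. Of 100 genes changed 3-fold 99 passed the rule, the other lying under 20 CPM, and 0 of the 100 changed 1.5-fold and 0 of the unchanged genes did. The simulated sums varied by counting error only, without differences between animals or libraries. They check the computing steps and do not show how often an unchanged gene passes 2-fold between real libraries. Alternatives to the scaling (including TMM factors from edgeR 4.0.16), the cell filters, doublet handling, depth, thresholds and clustering were run, and the closing section gives their effect. The stricter cell filter asked for 1000 genes and at most 5% mitochondrial UMIs. It took 4985 WT and 8701 KO-labelled cells, as the median mitochondrial share of kept cells was 4.94% and 4.35%. Clusters made with all variable genes kept those that differed between libraries, and still left out ribosomal, mitochondrial and sex-linked genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.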

Results

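Single-cell RNA-seq was carried out on LSK CD150+ cells sorted from mouse bone marrow. These are cells without lineage markers that carry Sca-1, Kit and the SLAM receptor CD150. By the clusters described below, cells like haematopoietic stem cells were only a part of this sort. The mice carried a Runx1 allele flanked by loxP sites together with Mx1-Cre, a recombinase gene that interferon signalling switches on. Whether and when an interferon inducer was given to either group is not given in the sources used here. There was 1 library labelled RUNX1 WT and 1 labelled RUNX1 KO, made from about 10000 sorted cells each, and the stated aim was to compare the make-up of the sorted population. The WT library held 9969 barcodes with 113732196 UMIs, of which 9472 cells were kept with a median of 9884 UMIs and 3035 genes per cell. The KO-labelled library held 11398 barcodes with 120578398 UMIs, of which 10769 cells were kept with a median of 9310 UMIs and 2811 genes. With 1 library per genotype no difference below has a replicate check and none was tested. Intervals are exact 95% intervals for counting error only.

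Runx1, the targeted transcription factor gene, was higher in the library labelled KO. It stood at 104 CPM in the WT library and 196 CPM in the KO-labelled library, a ratio of 1.89 (95% interval 1.85 to 1.93), and was higher in 14 of the 14 clusters with at least 50 cells in each library. Runx1 (ENSMUSG00000022952) lies on chromosome 16 from 92601466 to 92826149 on the minus strand of GRCm38. The counts come from 3′ tags, and the labels do not say which part of the gene is deleted, so tags outside that part check nothing about the genotype. Directions below are therefore those of the library labelled KO. Among the other measured members of the RUNX list, Runx2 had a ratio of 1.48 (1.42 to 1.55) and Runx3 of 1.27 (1.24 to 1.30), while Cbfb, which encodes the partner subunit of RUNX proteins, had a ratio of 0.788 (0.755 to 0.823). Over its 6 measured members the list had a median log2 ratio of 0.10, at percentile 97.4 of random lists, which was -0.14 with no floor on CPM and 0.34 at 20 CPM.

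The libraries also differed in the sex of their cells. Xist, the RNA of the inactive X chromosome, was at 1.78 CPM in the WT library and 1319 CPM in the KO-labelled library. In the KO-labelled library 8927 cells (82.9%) had at least 2 Xist UMIs and no UMI of 4 Y-linked genes, and 973 cells (9.04%) had a Y-linked UMI and no Xist UMI. In the WT library those numbers were 9 and 6690. With neither kind of UMI, 2748 WT cells (29.0%, median 7689.5 UMIs) and 439 KO-labelled cells (4.08%) were counted as neither sex. With the 973 male cells, gene ratios and counts, list medians, cluster class shares and the shares by megakaryocyte and G2 and M phase score were repeated between male cells, a comparison added after the data were seen. Of the 24 genes named by size below, 23 kept their direction between male cells, and Ighm did not (ratio 1.14).

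Genes of platelets and megakaryocytes did not move as a group but divided into lower and higher members in the KO-labelled library. Pf4, a platelet chemokine, stood at 1483 CPM in the WT library and 485 CPM in the KO-labelled library, 3.05-fold lower. Vwf, which encodes the adhesion protein von Willebrand factor, was 3.1-fold lower. Selp (ratio 0.534) and Mmrn1 (0.548) were also lower. Against these, Clec1b, the platelet receptor for podoplanin, was at a ratio of 4.0 (3.71 to 4.33), Treml1 at 2.33 and Gp5 at 2.06. Of 21 measured members of the list 10 were higher and 11 lower, 5 and 4 of them by at least 1.5-fold, and the median log2 ratio was -0.015 (percentile 89.6 of random lists), while the mean was 0.14. With equal cluster weights that median was 0.26. Pf4 was lower in 13 of 14 clusters and Vwf in 12 of the 12 clusters with enough counts. These clusters were made without genes that differed between libraries. In GMP-like cells, which should lack Pf4, thinned shares with a Pf4 UMI were 12.4% (WT) and 4.91% (KO-labelled). In erythroid-like cells they were 13.9% and 6.83%. For Vwf the GMP-like shares were 1.38% and 0.508%, and the erythroid-like shares 0.855% and 0.896%. Free Pf4 RNA, if higher in the WT library, would give the same direction in each cluster. That was not tested, so the count for Pf4 cannot show a change within each kind of cell. With equal weights for 8 clusters made with all variable genes, a comparison added after the data were seen that left out 53.6% of WT and 57.3% of KO-labelled cells, Pf4 was at 1.01, Selp at 1.07, Vwf at 0.683 and Treml1 at 5.12, and the list median was 0.52.

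Stem cell genes were split in the same way, with 8 of 16 measured members higher and 8 lower and a median log2 ratio of -0.0035 (percentile 90.1), which was 0.36 under the stricter cell filter. That filter took unequal parts of the libraries, 4985 of 9472 WT cells and 8701 of 10769 KO-labelled cells. Mecom, a transcription factor gene needed for stem cell maintenance, was 2.71-fold lower and was lower in 14 of 14 clusters, with a ratio of 0.678 for the clusters made with all variable genes. Cdkn1c (ratio 0.416) and Ctnnal1 (0.425) were lower, and Procr was at 0.749 but at 1.51 under the stricter cell filter and 1.49 for those clusters. After thinning, WT cells with a Procr UMI numbered 417 of 9317, and 55 of 4946 under the stricter filter. KO-labelled cells with a Procr UMI numbered 340 of 10678, and 162 of 8665 under that filter. The filter thus left out a larger part of the WT than of the KO-labelled cells with Procr. Slamf1, which encodes the CD150 antigen used in the sort, was at a ratio of 1.63 (1.55 to 1.73). Hlf, Gata2 and Meis1 had ratios between 0.930 and 1.01, and Hlf was at 1.3 under the stricter cell filter. In the list of stem cell ageing genes 7 of 15 measured members were higher and 8 lower, 2 and 5 of them by at least 1.5-fold. Vwf, Aldh1a1 (0.445), Nupr1 (0.478) and Selp were among the lower ones. The median over the 15 members was -0.0093 (percentile 88.8), which ran from -0.46 to 0.28 over the alternatives. For the clusters made with all variable genes Nupr1 was at 1.2 and Aldh1a1 at 0.705.

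Of 5904 genes at 20 CPM or more in either library, 133 were at least 1.5-fold higher and 120 at least 1.5-fold lower in the KO-labelled library. Past 2-fold 52 were higher and 36 lower. These counts follow a rule of size and are not calls. With equal weights for the clusters they were 30 and 29, and for the clusters made with all variable genes 27 and 16. The median log2 ratio over these genes was -0.070. TMM scaling, which differs by -0.098 on the log2 scale and makes all ratios higher, gave 68 and 31 genes past 2-fold. It put the medians of the stem cell (0.094), megakaryocyte (0.083), G2 and M phase (0.0071), interferon (0.066), p53 (0.074), transcription factor (0.060) and ageing (0.089) lists above 0. Without ribosomal and mitochondrial genes in the total the MHC class II median was -0.035. That smaller total makes all ratios higher, but it also raises CPM values, so that more genes pass the floors and enter.

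Among the 12 named genes with the highest ratios were Hmga2 (5.94), Lpcat2 (5.43), Fcgr2b (4.14), Tespa1 (3.85), Cpa3 (3.53), Fam189b (3.4), Gadd45g (3.17), Slc41a3 (2.98), Cd48 (2.83), Otos (2.83) and Tjp1 (2.53). Hmga2 encodes an architectural chromatin protein and went from 4.31 to 25.6 CPM. Cd48 encodes a SLAM family receptor that is absent or low on the most primitive stem cells. Beyond Fcer1a, described below, the lowest were Serpine2 (6.44-fold lower), Bex1 (5.02-fold), Tnip3 (4.80-fold), Bex4 (3.96-fold), Ighm (3.96-fold), Fkbp11 (3.44-fold), Vwf, Pf4, Trpc6 (2.83-fold), Selenom (2.75-fold) and Mecom. Of the 24 genes, 19 kept 1 direction in every cluster with enough counts (10 to 14 clusters). The exceptions were Fcgr2b, Gadd45g, Cd48 and Pf4, each with 1 cluster the other way, and Ighm, an immunoglobulin gene that was higher in 11 of 14 clusters and had a ratio of 1.13 with equal cluster weights. Ighm UMIs were found in 13.8% of WT and 24.7% of KO-labelled cells without thinning, against the direction of its CPM. Equal weights leave out cluster 19, led by other immunoglobulin genes, with 24 WT and 12 KO-labelled cells. In the 8 clusters made with all variable genes 12 of the 24 kept 1 direction in every cluster with enough counts, and 18 kept at least 1.5-fold with equal weights. There most ratios were nearer to 1, among them Hmga2 (3.69), Lpcat2 (2.23), Tespa1 (2.29), Cpa3 (2.33), Fcgr2b (1.95), Fam189b (1.91), Cd48 (1.36), Serpine2 (0.452), Bex1 (0.341), Tnip3 (0.487), Bex4 (0.402), Trpc6 (0.845) and Selenom (0.603).

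**Figure D1:**
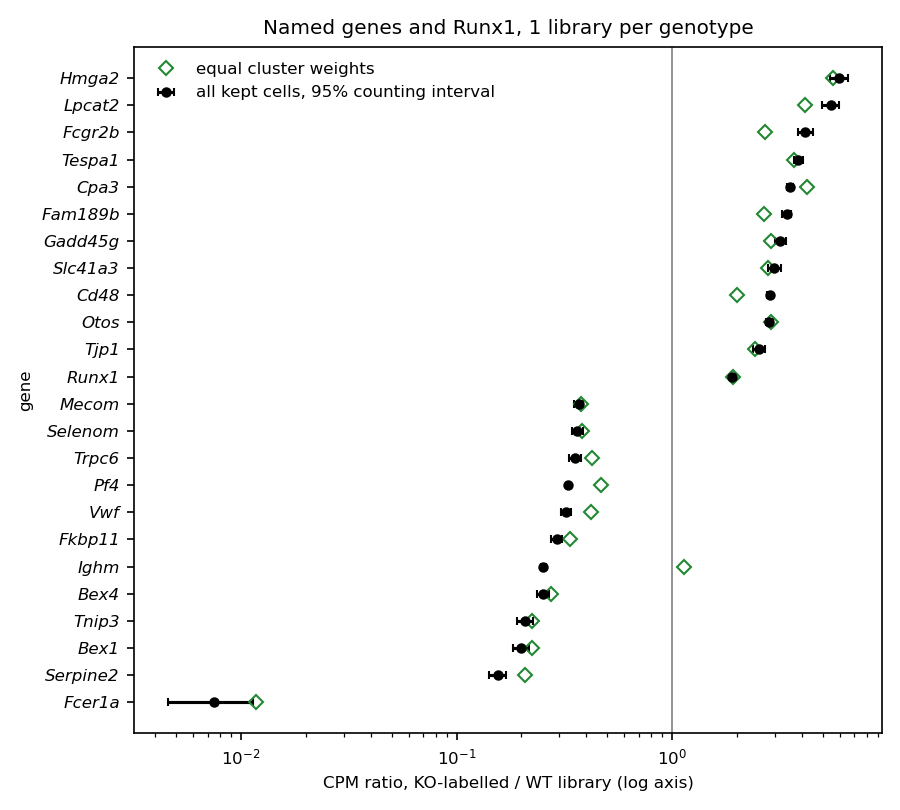
CPM ratio of the KO-labelled to the WT library on a log axis for 23 of the named genes and Runx1, 1 library per genotype, with black points for all kept cells (exact 95% counting intervals) and open diamonds for equal cluster weights. Ighm moves from 0.253 to 1.13 between them.

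Genes for receptors on stem and progenitor cells were mostly higher in the KO-labelled library, with 17 of 26 measured members of the niche and cytokine receptor list higher and a median log2 ratio of 0.19 (percentile 100 of random lists), which was 0.053 for the clusters made with all variable genes. Besides Cd48 these included Csf2rb (2.39, and 1.46 for those clusters) and Csf3r (1.92), which encode receptor chains for growth factors of granulocytes, and Cd34 (1.68). Kit, the stem cell factor receptor gene used in the sort, was at 0.937.

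Genes of granulocytes and red cells were higher in the KO-labelled library. All 10 measured genes of mature neutrophils were at least 1.5-fold higher, among them S100a8 (35.5 and 222 CPM) and Camp (16.1 and 101 CPM). Their median log2 ratio was 2.43 (percentile 100). It was 0.74 in clusters taking at least 5% of each library, which leave out the GMP-like cluster and clusters 13 and 16. Between male cells it was 4.07. Those were 6690 of 9472 WT cells with 121 of 1813 Camp UMIs, and 973 of 10769 KO-labelled cells with 763 of 12094. The neutrophil genes came from few cells. A UMI of S100a8 was found in 1.58% of WT cells and 3.82% of KO-labelled cells at 3000 UMIs per cell, against 1.11% and 2.30% in the Mk-like clusters, which should lack it (median 11364 and 12290 UMIs). Of 19 erythroid genes 16 were higher (median 0.48, percentile 100), led by the haemoglobin genes Hba-a2 (4.01) and Hbb-bs (3.87), while Klf1, a regulator of red cell genes, was at 1.10 and at 0.837 without the 5% deepest cells. A UMI of Hbb-bs was found in 3.06% and 6.03% of cells, against 2.99% and 5.25% in GMP-like cells, which should lack it, and 5.98% and 16.8% in erythroid-like cells. That class pools clusters 11, 12 and 15. Cluster 15, with haemoglobin genes among its leading genes, held 39 WT and 96 KO-labelled cells. Within clusters taking at least 5% of each library, which leave out all erythroid-like clusters, Hbb-bs had a ratio of 0.884 and the erythroid list a median of -0.16. Of 19 granulocyte and monocyte progenitor genes 13 were higher (median 0.28, percentile 100), with Mpo at 1.32 and Elane at 1.2, and Nkg7 was 1.94-fold lower. With equal cluster weights that median was 0.025 and Elane was at 0.836. Monocyte and dendritic cell genes had a median of 0.25 over 10 members (percentile 100), led by F13a1 (2.97, and 1.75 for the clusters made with all variable genes).

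Mast cell and basophil genes moved furthest apart. Fcer1a, the alpha chain of the high-affinity IgE receptor, had 23.6 CPM in the WT library and 0.176 CPM in the KO-labelled library, a ratio of 0.00746 (0.00461 to 0.0114). The basophil protease genes Mcpt8 (108 and 0.755 CPM) and Prss34 (109 and 0.0587 CPM) were also lower, with ratios of 0.00696 and 0.000539. With equal cluster weights, which leave out cluster 16, they were 9.70-fold and 86.8-fold lower. Of the Prss34 UMIs of the WT library, 11748 came from the 86 cells of cluster 16 and 520 from all others. Cpa3, a protease gene of mast cells and their progenitors, was 3.53-fold higher. The median over 8 members, 4 of them lower and 4 higher, was -0.71 (percentile 0), and it was 0.66 with equal cluster weights.

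Lymphoid-primed progenitor genes had 5 of 10 members higher and a median of 0.010 (percentile 87.5) that ran from -0.31 to 0.66 over the alternatives. Cd52 (1.73, and 1.07 for the clusters made with all variable genes) was higher and Mef2c (0.622) lower. Few members of the remaining lineage lists were measured. Both B cell genes gave a median of -0.85 (percentile 0.33), carried by Ighm, and that median was 0.28 with equal cluster weights. The macrophage list had a median of -0.46 (percentile 17.1) and the stromal list of -0.24 (percentile 22.2), each over 2 genes, and both turned above 0 under an alternative (up to 0.18 and 0.11). The only eosinophil gene measured, Prg2, was 6.38-fold lower (log2 ratio -2.67, percentile 0.11), with ratios from 0.0324 to 0.32 over the alternatives. Of the T and NK cell list no member reached 5 CPM.

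S phase genes were lower in the KO-labelled library. All 27 were lower, with a median log2 ratio of -0.26 (percentile 0), led by Uhrf1 (0.680) and Hells (0.731), which act in DNA methylation maintenance and chromatin remodelling, and Mcm2 (0.739), a subunit of the replicative helicase. With equal cluster weights the median was -0.13. Of 26 G2 and M phase genes 22 were lower, with a median of -0.091 that lay within the range of random lists (percentile 20.7) and was 0.0071 under TMM scaling and 0.067 in clusters taking at least 5% of each library. Top2a was at 0.827 and Mki67 at 0.911. Quiescence genes were mostly higher, 15 of 18 with a median of 0.28 (percentile 100) that was 0.052 for the clusters made with all variable genes. Txnip (1.58), Rgs1 (1.62) and the cell cycle inhibitor gene Cdkn2c (1.66) were higher, and Cdkn1c and Egr1 (0.649) lower. Of 16 immediate early genes 15 were higher (median 0.31, percentile 100), led by Fosb (2.09) and Fos (1.92).

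Among lists of general cell functions, 74 of 81 ribosomal protein genes were higher with a median of 0.13 (percentile 100). Ribosome biogenesis genes (32 of 36 lower, median -0.14, percentile 2.13), mitochondrially encoded genes (12 of 13 lower, median -0.16, percentile 1.43) and nuclear respiratory chain genes (58 of 73 lower, median -0.099, percentile 2.38) went the other way, and under TMM scaling their medians were -0.039, -0.064 and -0.0013. Heat shock genes had a median of -0.25 (percentile 0.41), with 8 of 10 lower, among them the chaperone genes Hsph1 (0.681) and Hsp90aa1 (0.783). All 6 measured Hox genes were lower with a median of -0.48 (percentile 0.09), led by Hoxa10 (0.531), although Hoxa7 (0.996) and Hoxa9 (0.925), the members at 20 CPM, were close to 1 and gave -0.059. Glycolysis genes had a median of 0.037 (percentile 97.7), with 12 of 20 higher, and -0.016 with equal cluster weights. NF-kB and inflammatory genes had a median of 0.087 (percentile 97.7). Interferon-stimulated genes had a median of -0.032 (percentile 89.3), p53 targets of -0.033 (percentile 71.6), haematopoietic transcription factor genes of -0.038 (percentile 81.1), MHC class I genes of 0.025 (percentile 90.8) and MHC class II genes of 0.015 (percentile 88.2), the last running from -0.34 to 0.34 over the alternatives. For the clusters made with all variable genes the interferon median was 0.17. Among transcription factor genes Lyl1 was at 2.03 and Mef2c at 0.622. The sex-linked list had a median of -2.56 over 6 genes (percentile 0). Means had the other sign for the p53 (0.081), transcription factor (0.034), glycolysis (-0.048) and sex-linked (0.22) lists.

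**Figure D2:**
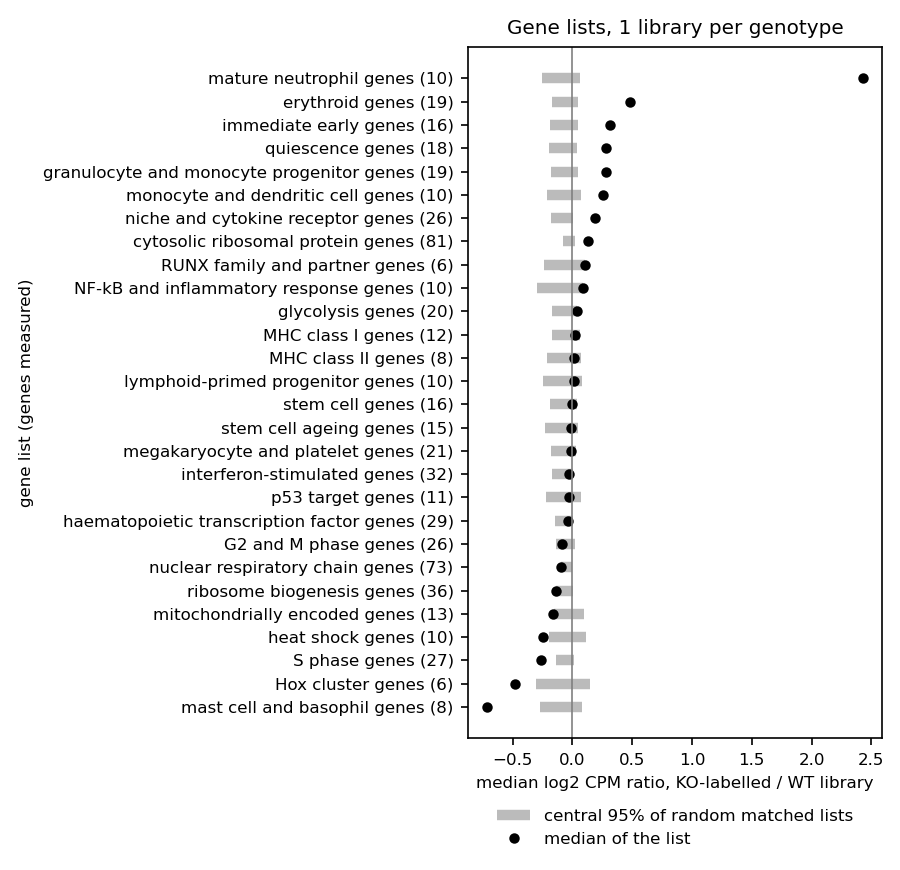
Median log2 CPM ratio of the KO-labelled to the WT library for each list with at least 5 measured genes other than the sex-linked genes, 1 library per genotype, with grey bars for the central 95% of 10000 random lists matched on expression. Mature neutrophil genes lie at 2.43 and mast cell and basophil genes at -0.71.

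Shares of cells with a UMI were compared after thinning each cell to 3000 UMIs, which left out 155 WT and 91 KO-labelled cells. Pf4 was found in 42.0% (41.0 to 43.0) of WT cells and 26.3% (25.4 to 27.1) of KO-labelled cells, and without thinning in 63.7% and 45.9%. In GMP-like cells, which should lack Pf4, the shares were 12.4% and 4.91% at median depths of 16408 and 16129 UMIs. Vwf was found in 8.10% and 2.87% of cells (20.6% and 8.39% unthinned), against 1.38% and 0.508% in GMP-like cells. Itga2b, the platelet integrin gene, went the other way with 32.2% and 40.8% (57.9% and 66.2% unthinned), against 8.51% and 7.78%. Cd48 was found in 14.7% of WT cells and 40.4% of KO-labelled cells (35.7% and 76.9% unthinned), and within HSC-like clusters in 6.74% and 50.6% at median depths of 6893 and 6988 UMIs, while GMP-like cells stood at 40.0% and 38.8%. No cluster class was low for Cd48 in both libraries. Slamf1 was found in 5.36% and 8.53% (17.4% and 23.7% unthinned), against 1.38% and 0.338% in GMP-like cells. It was higher in Mk-like (5.89% and 12.5%) and erythroid-like cells (2.56% and 9.74%) and lower in HSC-like cells (6.24% and 4.45%). Mki67 was found in 42.5% and 33.9% (57.8% and 47.4% unthinned), against 9.22% and 7.09% in HSC-like cells. Mpo was found in 10.6% and 11.7% (21.3% and 23.7% unthinned), against 5.05% and 4.75% in Mk-like cells.

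**Figure D3:**
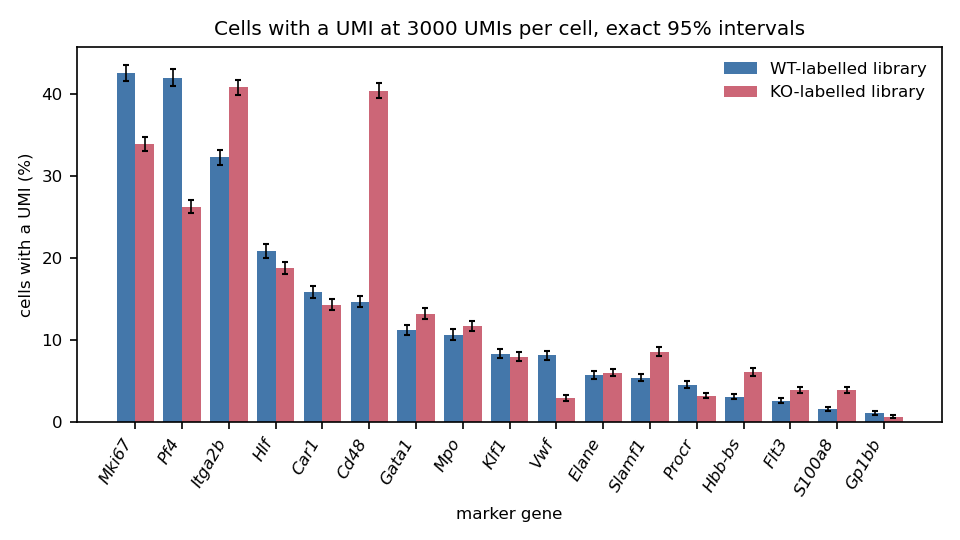
Share of cells with a UMI of each marker gene, in percent, after thinning to 3000 UMIs, with exact 95% intervals and 1 library per genotype. Cd48 stands at 14.7% in the WT library and 40.4% in the KO-labelled library, and Pf4 at 42.0% and 26.3%.

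Cells with at least 3 UMIs of the megakaryocyte list made up 58.0% (57.0 to 59.0) of WT cells and 59.1% (58.1 to 60) of KO-labelled cells, with 34.0% and 38.0% of cells near that limit at 2 to 4 UMIs. Cells with at least 3 UMIs of the G2 and M phase list made up 75.7% (74.9 to 76.6) and 69.1% (68.2 to 70.0), with 26.1% and 32.5% near the limit. Without thinning the latter shares were 92.1% and 92.3%. For the S phase list the shares were 85.4% and 74.8% at 3000 UMIs and 94.8% and 93.9% without thinning. Without thinning nearly all cells passed the G2 and M phase and S phase limits, which left little room for a difference. All of these are ranges of a score and not cell types.

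Joint clustering, made without genes that differed 1.5-fold or more between libraries, gave 19 clusters within the LSK CD150+ sort. Megakaryocyte-like cells, clusters 3 and 8 led by Pf4, Vwf, Clec1b and Tuba8, made up 23% (22.1 to 23.8) of the WT library and 12.6% (12 to 13.2) of the KO-labelled library, a ratio of 0.548 (0.512 to 0.587). The ratio lay between 0.409 and 0.885 over the alternative clusterings. Unlike the clustering, the naming used genes that differed between libraries, Pf4 and Vwf among them. WT cells made up 58.5% of cluster 3 and 66.2% of cluster 8, so the higher Pf4 and Vwf of that library could favour the name. HSC-like cells, clusters 1 and 7 with Procr, Ly6a and Mecom among their leading genes, made up 23.8% and 21.3%, a ratio of 0.894 that ran from 0.0983 to 1.13 over alternatives. The lowest value came without Scrublet calls, where 1 cluster took the name. There KO-labelled cells with the name went from 2291 to 136 although none was left out, so the value reflects clustering and naming. In the main clustering the HSC-like clusters went opposite ways. Cluster 1 took 14.2% and 15.4% (ratio 1.08), and cluster 7 took 9.59% and 5.85% (ratio 0.610). WT cells made up 59.0% of cluster 7. Mecom, lower in the KO-labelled library, was among its leading genes, so that could favour the name here too. Erythroid-like cells took 8.69% and 8.39%, and GMP-like cells, led by Elane, Mpo and Ctsg, took 4.61% and 5.49%. Cluster 2, unnamed and led by Gm17590, Fam189b and Tcp11l2, took 3.77% of the WT library and 18.3% of the KO-labelled library. As 84.7% of its cells came from 1 library, it may be that library and not a cell type.

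**Figure D4:**
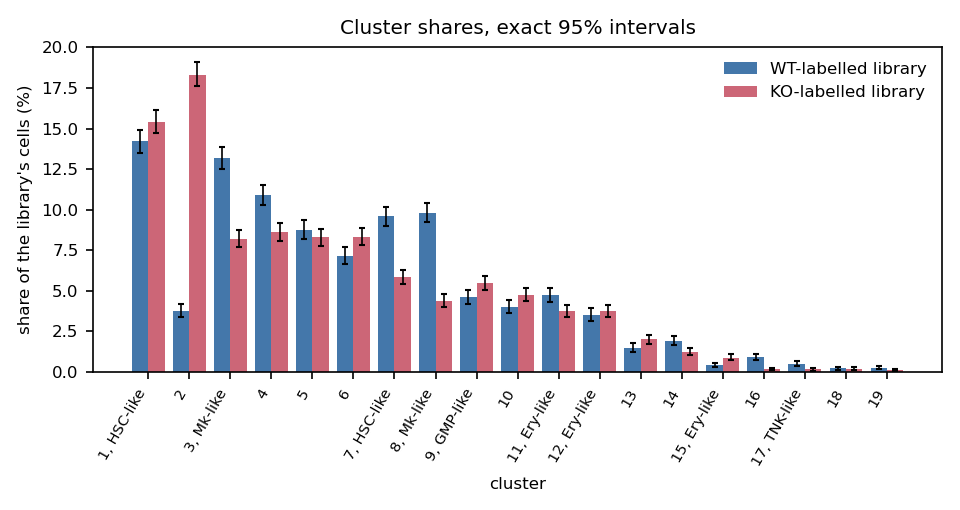
Share of each library's cells in each of 19 clusters, in percent, with exact 95% intervals and 1 library per genotype. Cluster 2 takes 3.77% of the WT library and 18.3% of the KO-labelled library, and the Mk-like clusters 3 and 8 are smaller in the KO-labelled library.

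**Figure D5:**
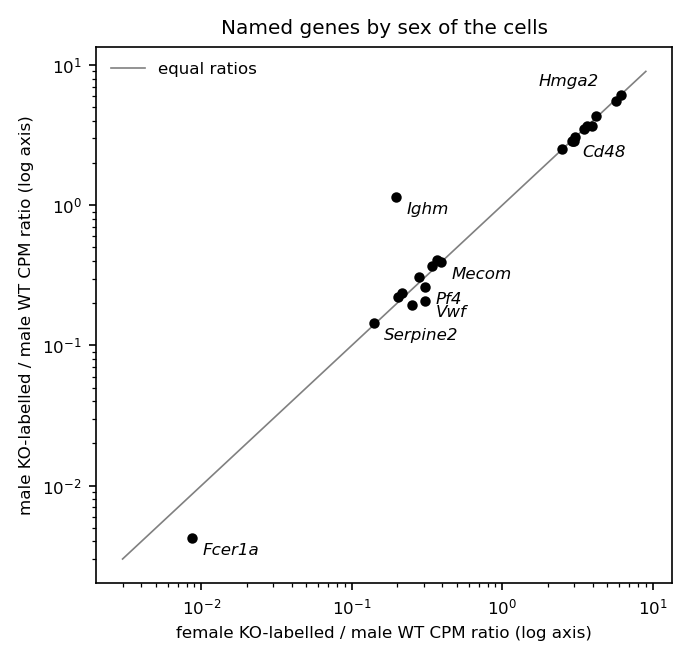
CPM ratios of 23 of the named genes on log axes for female (horizontal) and male (vertical) cells of the KO-labelled library, both over male WT cells. Points near the line have equal ratios, and Ighm lies apart at 0.196 and 1.14.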

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

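All tests in this part were chosen after the result was seen. A signal among sex-linked genes, which were left out of the genes named by size, stood out in the KO-labelled library: 85.1% of its kept cells had at least 2 Xist UMIs, against 13 of 9472 cells (0.137%) of the WT library. Another 973 KO-labelled cells had a Y-linked UMI and no Xist UMI, so that library holds cells of at least 2 animals. In 237 cells both kinds of UMI were present, with a median of 17791 UMIs against 9308 in female cells, although Scrublet called 0 doublets there.

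Because the WT library is male and most of the KO-labelled library female, sex was weighed as a source of the lower platelet genes and the higher Cd48 and Cpa3. Between male cells of both libraries 23 of the 24 named genes kept their direction, which argues against sex. Across 5738 autosomal genes, which are not independent replicates, log2 ratios of female and of male KO-labelled cells over the male WT cells had Pearson r = 0.954 and Spearman rho = 0.923. With no difference simulated, shared WT cells gave r = 0.245, and the covariance was 0.152 against 0.000560. With separate WT cells for each ratio r was 0.910. Male and female KO-labelled cells shared 1 library, so its free RNA and handling are common to both.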

How the results depend on the processing

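In this part the alternatives with male cells only, without Pf4, without the 6% highest Scrublet scores and with equal weights for clusters made with all variable genes were chosen after the results were seen. No paired analysis was possible because there was 1 library per genotype. The cause was not tested where a value below moved, except that another floor changes which genes enter and the cluster settings change which clusters enter. A total without ribosomal and mitochondrial genes is smaller, which raises CPM values, so more genes pass the floors there as well. Intervals cover counting error only, so small shifts count as moved. The ratio of S phase shares was 0.876 at 3000 UMIs and 0.990 unthinned, where shares of 94.8% and 93.9% left little room for a difference. With a limit of 5 UMIs at that thinned depth it was 0.769. The ratio of shares with a Mki67 UMI was 0.797 thinned and 0.820 unthinned. Thinning, which also gives cells equal weight, moved list medians as given below. Among single genes, markers and the other lists 1229 values moved, 19 reversed and 1171 stayed within their interval. Reversed here means a turn of direction in a gene or share at least 1.5-fold from 1, or a list outside the central 95% of random lists. Counting values nearer to no difference as well, 140 values of 53 results turned, 22 of them reversed, among the others those of Procr, Elane, Klf1, Hlf and the stem cell, megakaryocyte, G2 and M phase, RUNX, MHC class II, ageing and lymphoid-primed lists.

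Of values called by that rule, reversed were, between male cells, Tsix (0.298), Eif2s3y (1.23), Ddx3y (1.01), Ighm (1.14) and the B cell list (0.27). With equal cluster weights, which leave out clusters 15 to 19, they were Ighm (1.13), the B cell list (0.28), the mast cell and basophil list (0.66) and the glycolysis list (-0.016). Clusters with 5% of each library leave out the erythroid-like and GMP-like clusters and cluster 16. There they were Hbb-bs (0.884), Hbb-bt (0.725), Ighm (2.20) and the erythroid (-0.16), B cell (0.68) and mast cell and basophil (1.96) lists.

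The Runx1 ratio was 1.94 with the stricter cell filter, 1.98 without the 5% deepest cells, 1.85 in the 5% clusters, 1.97 with median-ratio scaling, 1.96 without ribosomal and mitochondrial genes, 2.02 with TMM and 1.75 between male cells. Higher and lower genes numbered 30 and 29 with equal cluster weights, 909 and 1845 with no floor and 29 and 15 at 50 CPM. They numbered 80 and 53 without ribosomal and mitochondrial genes in the total, where more genes passed 20 CPM.

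With equal weights for clusters made with all variable genes, reversed were Selp (1.07), Hmox1 (1.41), Nupr1 (1.2), Pf4 (1.01), Ighm (1.09) and the B cell (0.34) and glycolysis (-0.015) lists. Runx1 was at 1.98, 27 genes were higher and 16 lower, and the medians were 0.28 (stem cell), 0.52 (megakaryocyte), 0.18 (erythroid), 0.041 (granulocyte and monocyte progenitor), 2.54 (neutrophil), -0.27 (mast cell and basophil) and -0.067 (G2 and M phase).

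In the order stricter filter, without the deepest cells, thinned, equal weights, 5% clusters, median-ratio scaling, TMM and male cells, the stem cell median was 0.36, 0.021, -0.12, -0.042, -0.095, 0.055, 0.094 and 0.037, the erythroid median 0.36, 0.24, 0.34, 0.15, -0.16, 0.54, 0.58 and 0.27, and the G2 and M phase median -0.21, -0.13, -0.17, -0.0037, 0.067, -0.032, 0.0071 and -0.13. The stem cell median was 0.023 without Scrublet calls, 0.031 at 20 CPM and -0.25 with no floor. The erythroid one was 0.54 without ribosomal and mitochondrial genes and 0.28 at 20 CPM, and the G2 and M phase one -0.036 without ribosomal and mitochondrial genes.
The megakaryocyte median was -0.12 (stricter filter), 0.14 (without deepest cells), 0.16 (thinned), 0.26 (equal weights), 0.044 (median ratio), 0.014 (without ribosomal and mitochondrial genes), 0.083 (TMM) and -0.10 (male).
The granulocyte and monocyte progenitor median was 0.24 (stricter filter), 0.17 (Scrublet), 0.092 (without deepest cells), 0.15 (thinned), 0.025 (equal weights), 0.36 (5% clusters), 0.37 (without ribosomal and mitochondrial genes), 0.38 (TMM), 0.49 (male) and 0.24 (20 CPM).
The neutrophil median was 2.24 (stricter filter), 2.27 (Scrublet), 2.37 (without deepest cells), 2.33 (thinned), 0.74 (5% clusters), 2.53 (TMM), 4.07 (male), 2.54 (20 CPM) and 2.31 (no floor).
The mast cell and basophil median was -1.0 (stricter filter), -0.56 (male), -7.12 (20 CPM) and -1.85 (no floor).
The S phase median was -0.29 (without deepest cells), -0.34 (thinned), -0.13 (equal weights), -0.14 (5% clusters), -0.21 (median ratio), -0.21 (without ribosomal and mitochondrial genes) and -0.17 (TMM).

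The ratio of Mk-high shares was 0.946 at 5 UMIs, 1.06 without Pf4, 0.976 with shallower thinning to 2000 UMIs and 0.979 with the stricter filter. That of cycling shares was 0.959 and 0.835 at 2 and 5 UMIs, 0.858 and 0.963 with thinning to fewer and to more UMIs, 1.0 unthinned and 0.841 with the stricter filter. The HSC-like ratio was 0.342 at resolution 1.2, 1.13 with fewer variable genes, 0.731 with all variable genes kept and 0.0983 without Scrublet calls. In the last setting no KO-labelled cell was left out but fewer clusters took that name. The Mk-like ratio was 0.768 and 0.647 at resolutions 0.5 and 1.2, 0.885 with 15 components, 0.846 with fewer variable genes, 0.409 with all variable genes kept, 0.714 without Scrublet calls and 0.478 between male cells. With all variable genes kept 12 of the 24 named genes had 1 direction in every cluster.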

Other observations

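In this part the test of gene positions and the Runx1 ratio with equal cluster weights were fixed beforehand, and the other tests, and the bounds for that ratio, were chosen after the results were seen. A basophil-like group was present in the WT library and nearly missing in the KO-labelled one. Cells with at least 10 UMIs of Prss34 and Mcpt8 together numbered 74 of 9472 in the WT library (0.781%, 0.614 to 0.980) and 1 of 10769 in the KO-labelled library (0.00929%, up to 0.0517). Within cluster 16, 86 WT cells had 19811 CPM of Prss34 and 1695 CPM of Fcer1a, and its 19 KO-labelled cells had 0 CPM of either. Neutrophil genes (Ltf, Ngp, Camp) also led that cluster, so it holds more than 1 kind of cell. Outside that cluster Cpa3 (ratio 5.13), Ms4a2 (3.18) and Hdc (2.64) were higher in the KO-labelled library, Csrp3 was lower (0.264) and Gata2 was level (0.999).

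Fcer1a UMIs also lay outside that cluster in the WT library. At 3000 UMIs per cell they were found in 4.03% of Mk-like, 1.15% of GMP-like, 1.04% of HSC-like and 0.488% of erythroid-like WT cells. Free RNA from basophil-like cells would keep Fcer1a and Prss34 in 1 ratio, but there were 37.2 times as many Fcer1a UMIs per Prss34 UMI outside cluster 16 as inside, which argues against it. Without the cells of cluster 16 the ratio of Fcer1a was 0.0120 (0.00738 to 0.0183), and that of Prss34 was 0.0127 (0.00507 to 0.0263). Free RNA of the left-out cells stays in, so this ratio alone cannot decide whether only that cluster was lost. Only together with the excess of Fcer1a over Prss34 does it argue against loss of that cluster alone. No biological explanation was tested.

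For the lower platelet genes and higher Cd48 and Cpa3, a different mix of clusters was weighed. With equal weights for the clusters made without differing genes, 23 of the 24 named genes kept a ratio of at least 1.5. The shares of those clusters alone thus do not account for these ratios. As the 24 genes were left out of that clustering, it cannot decide on a mix of cells that differ in them. With equal weights for the 8 clusters made with all variable genes, 18 kept such a ratio. Pf4 (1.01), Vwf (0.683), Mecom (0.678) and Cd48 (1.36) were among the others. As these genes helped to define those clusters, which left out 53.6% of WT and 57.3% of KO-labelled cells, a different mix of them stays open. DNA of another strain carried along with the target was weighed by gene position. Of the genes with a ratio of 2 or more, 1.14% (Il10rb alone among 88) lay within 20 Mb of Runx1, against 0.644% of all genes at 20 CPM. So genes near the target made up little of the pattern. As that window held 38 of 5900 genes, the majority set as the mark of this explanation was out of reach. Effects of carried DNA on genes elsewhere were not examined, so it stays open. A difference in strain elsewhere in the genome, which was not examined, or between libraries or animals other than genotype cannot be told apart from genotype, because there was 1 library per genotype.

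For the higher Runx1 count of the KO-labelled library a different mix of clusters was weighed. The ratio was 1.92 with equal weights for the clusters made without differing genes, Runx1 among them. For the 8 clusters made with all variable genes, which left out 53.6% of WT and 57.3% of KO-labelled cells, it was 1.98. Both values argue against a different mix of these clusters. Swapped labels cannot be told apart from the labels as given, because the ratio of 1.89 rests on 3′ tags whose place relative to the deleted part is not given in the sources used here.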
